A study of Mus musculus with 9 samples.

How the data were processed

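The data are gene counts from RNA sequencing of 9 libraries of primary mouse myoblasts with floxed Uqcrfs1, 3 of floxed cells (adenovirus for green fluorescent protein) with vehicle, 3 of knockout cells (adenovirus for Cre) with vehicle and 3 of knockout cells with 7.5 µM oxybutynin for 5 days. Per the labels' protocols, total RNA was extracted with Trizol and directional libraries were made from 2 µg of RNA with a NEBNext kit. The deposited values are whole-number counts per gene, not normalized. Per the submitters' processing notes, Trim Galore 0.6.0, cutadapt, FastQC, STAR 2.7.0e and DESeq2 1.26.0 were used with the builds GRCm38 and mm10. The step that made the counts, its strand setting and the annotation release are not given in the sources used here. All 55536 gene IDs of the table are in GENCODE M21 (GRCm38), which gave coordinates, gene types, exon lengths and GC content, and 55450 had a symbol in the name table, leaving 86 without. No row lacked a gene and 0 columns lacked a sample. The reads were not analysed here.

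Library totals ran from 19604971 to 26226949 counts. Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 3 groups (15720 genes), libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit, glmQLFTest) was fitted to all 9 libraries with 1 mean per group and no covariate, which left 6 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the tested genes, and a gene is called at an adjusted p under 0.05. SEs of log2 fold changes came from the same fit. CPM values are counts-per-million of the TMM-scaled library. The 3 comparisons were knockout vehicle with floxed vehicle, knockout oxybutynin with knockout vehicle, and knockout oxybutynin with floxed vehicle. Groups with separate values are those whose ranges do not overlap. Shares of counts per library were compared by exact two-sided permutation tests.

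Gene lists were written before the data were examined, as were the design, the naming rule and the first set of alternatives. The 36 lists were complex III subunits and assembly factors, complex I nuclear subunits, nuclear subunits of complexes II, IV and V, mitochondrially encoded genes, mitochondrial ribosomal proteins, mitochondrial folding and proteases, tricarboxylic acid cycle, integrated stress response (ATF4) targets, serine and one-carbon metabolism, aspartate and nucleotide synthesis, endoplasmic reticulum unfolded protein response, glycolysis and lactate, hypoxia (HIF) targets, S phase, mitosis, G1 cyclins and CDK inhibitors, p53 targets, satellite cell and myoblast identity, myogenic differentiation and sarcomere, cholesterol synthesis, fatty acid synthesis, LXR targets, fatty acid oxidation, lysosome, NRF2 targets, interferon-stimulated genes, senescence-associated secretory genes, collagen and matrix, muscarinic receptors, cytosolic ribosomal proteins, and markers of fibroblasts, smooth muscle, endothelium, leukocytes, adipocytes and Schwann cells. The 33 lists with at least 5 tested members were tested by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and by fry. Members were counted at an adjusted p under 0.05 over all genes and adjusted over the list alone. Hypoxia shares 2 genes with glycolysis, aspartate and nucleotide synthesis shares 2 with S phase, satellite cell identity shares 1 with smooth muscle, and ATF4 targets share 1 each with p53 and NRF2 targets. The unfolded protein response shares 1 with hypoxia, serine and one-carbon metabolism 1 with S phase, and G1 cyclins and CDK inhibitors 1 with p53 targets.

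The text names Uqcrfs1; the 10 largest rises and falls with knockout and with oxybutynin (5 for the last comparison) among called genes with a mean of at least 10 CPM, no overlap between groups and a symbol that is not a clone name; up to 4 called members per list with the lowest adjusted p and well-known uncalled members; up to 6 genes called with opposite and 4 with the same sign in the first comparisons; and Chrm1 to Chrm5, Cdkn1a, Myog, Myod1, Pax7 and Mki67. Further genes are said to be chosen after their values were seen. Genes of the mitochondrial genome have nuclear copies that can share their reads, and genes that overlap on opposite strands cannot be told apart without the strand setting.

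That first set was DESeq2 1.42.0 (Wald test, NA adjusted p-values left as NA), limma-voom, RLE scaling, library totals as the only scaling, no filter beyond genes with 0 counts, a mean of at least 1 CPM, removal of mitochondrially encoded genes, a fit of only the 2 groups compared, leaving out each library in turn, an adjusted p under 0.01, a change of at least 1.5-fold, camera with an estimated correlation, and fry. Added after seeing the data were protein-coding genes only, an adjusted p under 0.1, and removal of the GC and length trend, with and without knockout vehicle replicate 2. For this, the deviation of each library's log2 CPM from the 9-library mean was fitted over protein-coding genes by natural splines of 5 degrees of freedom each on exonic GC content and log2 exon length, and the fit was used as an offset in edgeR and subtracted before camera. All 10 splits of the 6 libraries of each comparison into groups of 3 were fitted. Covariances of fold changes were set beside 100 simulations of unchanged groups and beside all other groupings of the knockout libraries, a test chosen after the result was seen. The edgeR test of each comparison was tried on simulated counts drawn from the real means and library sizes with 200 changed genes. Camera with the preset correlation was tried for oxybutynin against vehicle on separate simulated counts in which a single list was raised. The other tests of genes and lists were not tried in this way. Of unchanged genes, 7 of 15256 were called for knockout against floxed vehicle, 7 of 15233 for oxybutynin against vehicle and 14 of 15277 for knockout oxybutynin against floxed vehicle, and a list raised 1.2-fold was called (adjusted p = 3.98e-11) with 0 other lists. The simulated genes varied independently of each other. The simulations therefore cannot show how often lists are called wrongly when their genes vary together. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.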

Results

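RNA sequencing counts were collected from primary mouse myoblasts, the dividing precursors of skeletal muscle fibres, whose Uqcrfs1 alleles were floxed. Uqcrfs1 encodes the Rieske iron-sulphur protein, the catalytic subunit of mitochondrial complex III that takes electrons from ubiquinol. Cells infected with an adenovirus for green fluorescent protein kept the gene and are called floxed, and cells infected with an adenovirus for Cre recombinase are called knockout. Cells were seeded 72 h after infection and treated 24 h later for 5 days with 7.5 µM oxybutynin, an antagonist of muscarinic acetylcholine receptors, or with its vehicle DMSO. The 9 libraries formed 3 groups of 3, floxed with vehicle, knockout with vehicle and knockout with oxybutynin. No floxed cells received oxybutynin, so a dependence of the drug response on genotype could not be tested, and genotype went together with the virus given. Library totals were 19604971, 23140202 and 22702654 counts in floxed vehicle, 21257482, 22171649 and 25041550 in knockout vehicle, and 26226949, 25576941 and 22272829 in knockout oxybutynin. Nothing in the labels says that the replicates were separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Unless said otherwise, errors are SD for counts-per-million (CPM) values and SE for log2 fold changes, with n = 3 libraries per group.

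Uqcrfs1 (ENSMUSG00000038462) lies on the minus strand of chromosome 13, from 30540308 to 30545362 in GRCm38, and has 1 annotated transcript of 2 exons. Exon 1 spans 30545034 to 30545362 and exon 2 spans 30540308 to 30541341. The floxed vehicle libraries held 1539, 1781 and 1881 counts of the gene, the knockout vehicle libraries 51, 51 and 70, and the knockout oxybutynin libraries 71, 69 and 46. These were 79.6 ± 3.67, 2.45 ± 0.356 and 2.56 ± 0.437 CPM. The fall from floxed to knockout vehicle was 32.4-fold (log2 fold change -5.02 ± 0.13, adjusted p = 7.5e-14). Every knockout library held between 2.60% and 3.64% of the floxed mean, as the labels of all 9 libraries require. Oxybutynin left a log2 fold change of 0.07 ± 0.16 between the knockout groups (adjusted p = 0.82). Which exon was floxed is not given in the sources used here, so whether the remaining counts are of undeleted sequence or of undeleted cells was not determined.

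Several measures of the libraries moved with the groups. Transcripts of the mitochondrial genome took 3.11 ± 0.0333% of counts in floxed vehicle, 2.23 ± 0.417% in knockout vehicle and 1.78 ± 0.294% in knockout oxybutynin libraries. Ribosomal RNA loci took 8.07 ± 0.327%, 9.79 ± 2.10% and 12.1 ± 1.69%, and the small nuclear RNA Rn7sk took 2.04 ± 0.0949%, 3.13 ± 0.668% and 3.59 ± 0.342%. In exact two-sided permutation tests of 3 libraries against 3, where 0.1 is the smallest p possible, the difference between knockout and floxed vehicle gave p = 0.1 for the mitochondrial share, 0.4 for ribosomal RNA loci and 0.1 for Rn7sk. The 12 such tests had Benjamini-Hochberg values between 0.2 and 0.5. Fold changes also followed the base composition of transcripts. Across 12976 protein-coding genes, which are not independent replicates, the Spearman correlation of log2 fold change with exonic GC content was 0.542 for knockout against floxed vehicle, 0.690 for oxybutynin against vehicle in knockout cells and 0.635 for knockout oxybutynin against floxed vehicle. Lists called in the first 2 comparisons are therefore also given after an adjustment that was chosen after seeing the data. So are lists of all 3 comparisons whose call it changed. The adjustment removed each library's trend on GC content and exon length. That trend was fitted without regard to group, so a real difference between groups that runs with GC content or length is removed too. Knockout vehicle replicate 2 stood apart, with 2.71% mitochondrial counts against 2.04% and 1.95% in the other knockout vehicle libraries and a lower place on the first principal component (17.3 against 37.7 and 43.3). Knockout vehicle replicate 3 lay nearer the oxybutynin libraries than its own group. Its Pearson correlation of log2 CPM was 0.9930, 0.9924 and 0.9927 with oxybutynin replicates 1 to 3, and 0.9898 and 0.9862 with knockout vehicle replicates 1 and 2.

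**Figure D1:**
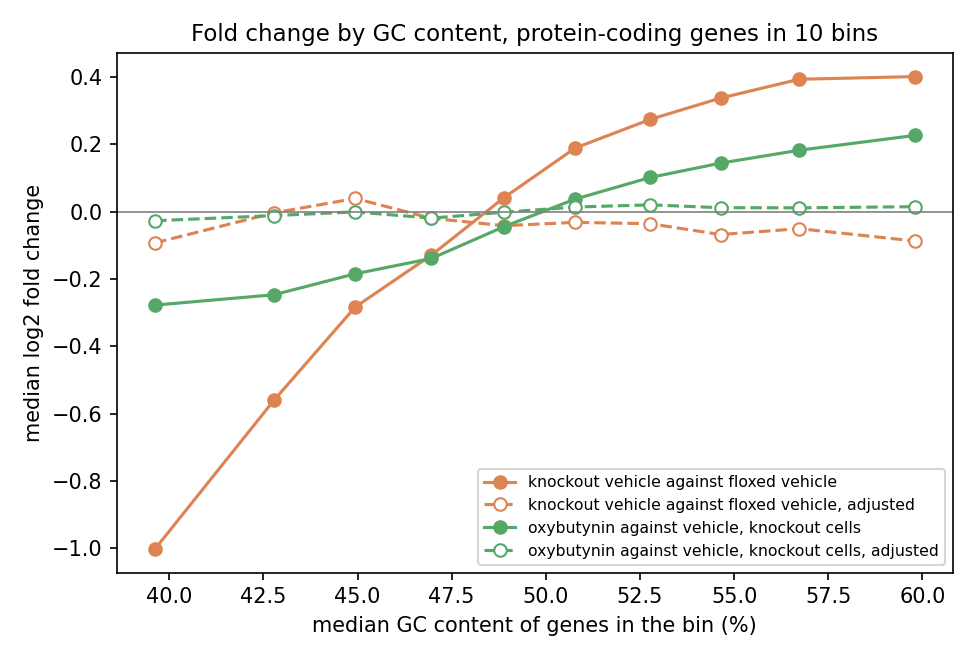
Median log2 fold change (vertical axis) of protein-coding genes in 10 bins of exonic GC content (horizontal axis, percent), before (solid) and after (dashed) removal of each library's trend on GC content and exon length. The comparisons drawn are knockout against floxed vehicle and oxybutynin against vehicle in knockout cells. For knockout against floxed vehicle the bin medians ran from -1.0 at 39.6% GC to 0.40 at 59.8% GC before the adjustment.

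**Figure D2:**
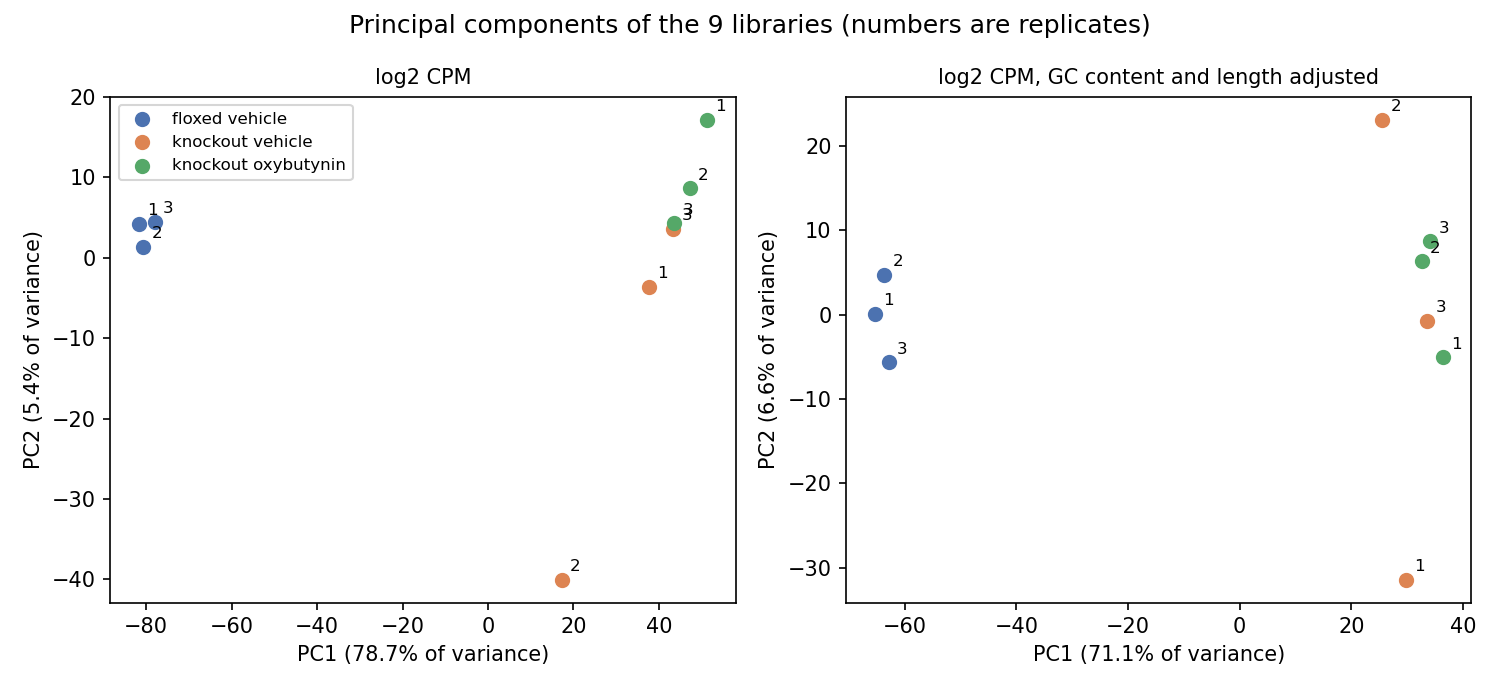
Principal components of the log2 CPM of the 9 libraries before and after the GC and length trend was removed, with axes giving each component's share of the variance and 1 point per library, marked by group. The first component held 78.7% of the variance before and 71.1% after, and knockout vehicle replicate 2 lay at 17.3 on it before the adjustment, against 37.7 and 43.3 for the other knockout vehicle libraries.

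To address what loss of the complex III subunit did to the transcriptome of untreated cells, knockout vehicle was compared with floxed vehicle. Ddit3, which encodes the stress transcription factor CHOP, rose from 6.13 ± 0.567 to 47.6 ± 4.95 CPM, and Gdf15, a secreted stress hormone, from 12.5 ± 0.733 to 107 ± 21 CPM. Hk2, the hexokinase that starts glycolysis, rose from 51.2 ± 1.96 to 179 ± 7.80 CPM. Mki67, the proliferation marker Ki-67, fell 6.59-fold from 605 ± 42.7 to 91.9 ± 7.57 CPM, and Mef2c, a transcription factor of muscle differentiation, fell from 171 ± 8.74 to 42.3 ± 3.36 CPM. Of 15720 genes tested, 9957 (63.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 4701 higher and 5256 lower in knockout. Of these, 3838 differed at least 2-fold, 1355 higher and 2483 lower. Of all 15720 genes tested, 10480 (66.7%) had no overlap between the groups, where chance gives 10% on average over splits. After the GC and length adjustment 9510 genes were called, of which 6981 were called in both fits and 460 of those with the opposite sign. In counts simulated at these depths, with genes drawn independently, the same test recovered 46% of genes changed 1.5-fold and 84% of genes changed 2-fold.

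**Figure D3:**
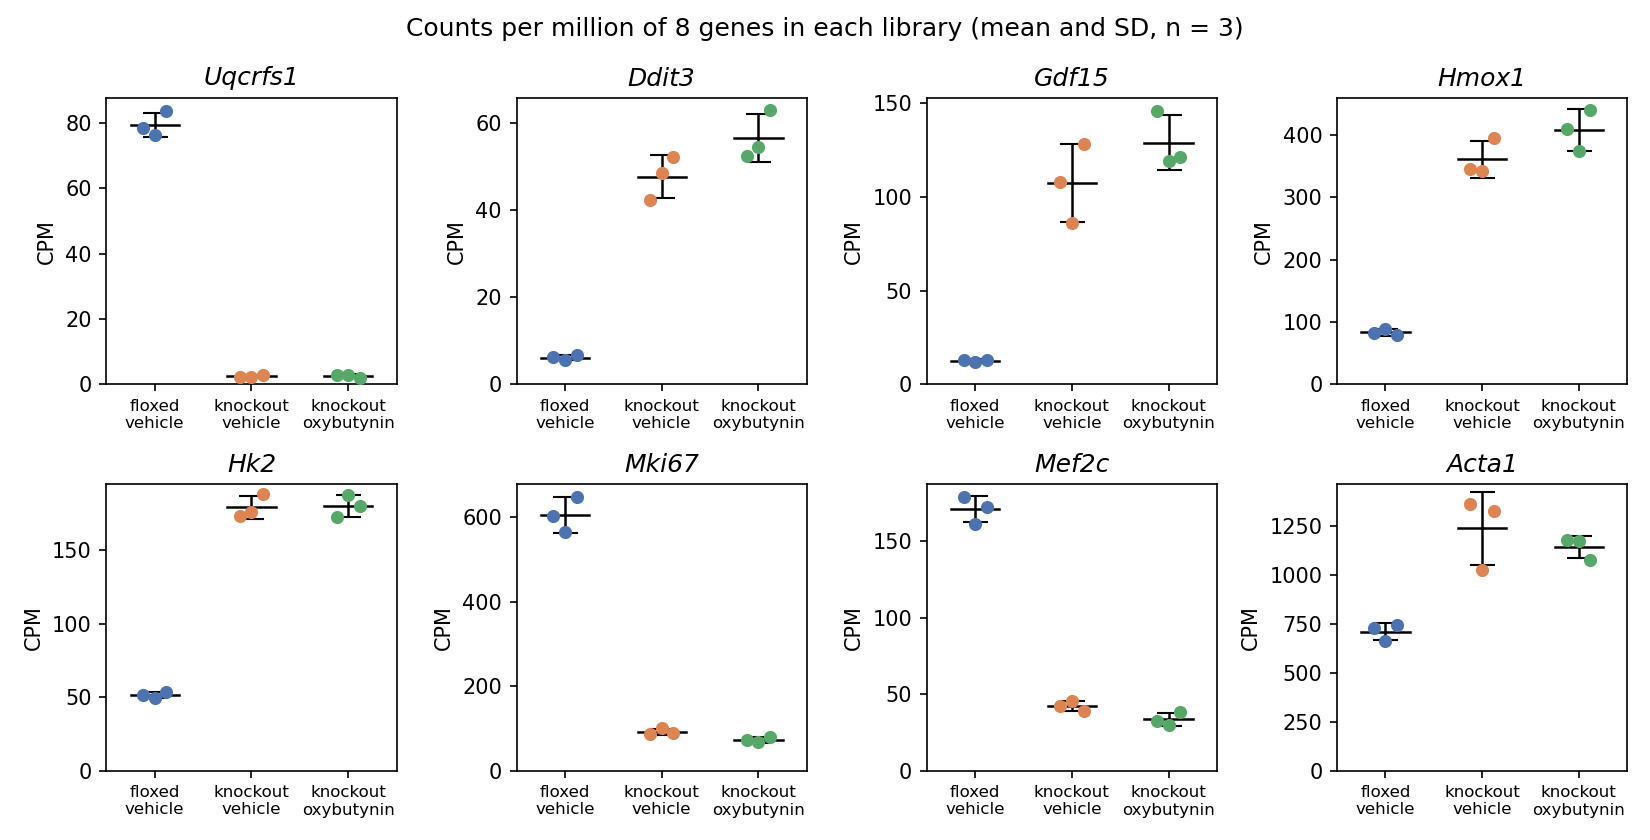
CPM (vertical axes) of Uqcrfs1, Ddit3, Gdf15, Hmox1, Hk2, Mki67, Mef2c and Acta1 in each library (points) of the 3 groups (horizontal axes), with bars at the group mean and error bars of 1 SD (n = 3). Uqcrfs1 averaged 79.6 CPM in floxed vehicle, 2.45 in knockout vehicle and 2.56 in knockout oxybutynin libraries, and Mki67 averaged 605, 91.9 and 72.9.

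The largest rise with knockout among genes of at least 10 CPM was that of Cdsn, the adhesion protein corneodesmosin, at 19.2-fold (log2 fold change 4.26 ± 0.16, from 5.05 ± 0.266 to 96.9 ± 23.1 CPM). Xdh, the xanthine dehydrogenase of purine breakdown, rose 17.7-fold (4.15 ± 0.14), and Acot2, a mitochondrial acyl-CoA thioesterase, rose 13.6-fold (3.76 ± 0.10). The iron exporter Slc40a1 (3.31 ± 0.15), the aminopeptidase Anpep (3.29 ± 0.14), the matrix metalloproteinase Mmp19 (3.29 ± 0.11), the muscle F-box protein Fbxo40 (3.27 ± 0.16) and the cationic amino acid transporter Slc7a3 (3.26 ± 0.15) followed, with Sh2d6 at 3.69 ± 0.22. After Uqcrfs1 itself, the largest falls were those of the Rab escort gene Chml (-2.81 ± 0.11), the cilium gene Cep290 (-2.78 ± 0.15), the integrin gene Itgb8 (-2.77 ± 0.15), Mki67 (-2.72 ± 0.10) and the neurofilament gene Nefl (-2.64 ± 0.11). Rfx3, a transcription factor of cilium genes, fell by 2.62 ± 0.14 and Casp8ap2 by 2.60 ± 0.15. The GC and length adjustment brought Chml to -1.97, Cep290 to -1.65, Itgb8 to -1.80, Rfx3 to -1.64 and Casp8ap2 to -1.83, and left Nefl at -2.81. Kcnq1ot1, an antisense RNA, had a log2 fold change of -2.60 ± 0.15, which is uncertain because the strand setting of the counting is not given.

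Targets of ATF4, the transcription factor of the integrated stress response, rose together. Of 34 measured members 31 rose, 1 fell and 2 were not called, and adjusted over the list alone 32 rose and 1 fell. Trib3, a pseudokinase induced by ATF4, rose by a log2 fold change of 3.26 ± 0.14, Gdf15 by 3.10 ± 0.13 and Ddit3 by 2.96 ± 0.12. Cth, an enzyme of cysteine synthesis, rose by 2.66 ± 0.11 and Atf4 itself by 1.13 ± 0.09. The list mean was 1.5 (camera with a preset correlation, adjusted p = 5.53e-13; adjusted p = 0.156 with an estimated correlation) and 1.29 after the GC and length adjustment. In serine and one-carbon metabolism 9 of 17 genes rose and 5 fell, over the list alone too, but the list was not called (adjusted p = 0.148). Aldh1l2 (1.85 ± 0.09), Psph (1.59 ± 0.11) and Mthfd2 (1.11 ± 0.08) were among the higher genes. Mitochondrial chaperones and proteases went both ways. Of 15 genes 8 rose and 4 fell (9 and 4 adjusted over the list alone; list adjusted p = 0.102). The protease Lonp1 (1.69 ± 0.09) and the co-chaperone Dnaja3 (1.09 ± 0.08) were higher and the protease Yme1l1 (-1.51 ± 0.11) and the chaperonin Hspd1 (-0.81 ± 0.10) lower. In the unfolded protein response of the endoplasmic reticulum 10 of 21 genes were higher and 4 lower, over the list alone too (list adjusted p = 0.174), and 9 were higher and 9 lower after the GC and length adjustment (median -0.04). Herpud1 (1.90 ± 0.10) rose, while the chaperone genes Hsp90b1 (-1.10 ± 0.11) and Dnajc3 (-1.16 ± 0.08) fell.

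Glycolysis genes rose, 20 of 22 with 0 lower, and the same numbers adjusted over the list alone. Their mean was 0.86 (camera adjusted p = 2.23e-06; adjusted p = 0.234 with an estimated correlation) and 0.59 after the GC and length adjustment. Hk2 rose by 1.81 ± 0.08, the lactate exporter Slc16a3 by 2.49 ± 0.22, the glucose transporter Slc2a1 by 1.44 ± 0.08 and Pdk1, which inhibits pyruvate dehydrogenase, by 1.29 ± 0.09. Targets of the hypoxia-inducible factor, which share 2 genes with the glycolysis list, rose in 13 of 17 cases and fell in 2 (14 and 2 adjusted over the list alone). The vasodilator peptide gene Adm (3.30 ± 0.21), the repressor Bhlhe40 (2.52 ± 0.12) and Ndrg1 (1.77 ± 0.11) were higher. The hypoxia mean was 1.16 (camera adjusted p = 4.48e-05; adjusted p = 0.0943 with an estimated correlation; adjusted mean 1.07). Fatty acid oxidation rose too, 11 of 17 genes higher and 2 lower in both countings. The mean was 0.53 (camera adjusted p = 0.0152; adjusted p = 0.234 with an estimated correlation; adjusted mean 0.51). In that list the uncoupling protein Ucp2 (2.29 ± 0.11), the acyl-CoA dehydrogenase Acadvl (1.16 ± 0.10) and Pdk4 (1.12 ± 0.11) rose, and Ppargc1a, a coactivator of mitochondrial biogenesis, fell from 46.8 ± 2.10 to 19.6 ± 1.42 CPM. In the tricarboxylic acid cycle pyruvate carboxylase Pcx rose by 1.95 ± 0.12, and 10 of 19 genes were higher and 4 lower in both countings. That list was called after the GC and length adjustment (mean 0.23, adjusted p = 0.0297, or 0.17 with an estimated correlation) and not before it (0.102). It was also called by DESeq2 (0.00783), with no filter (0.0231) and by fry (6.68e-05). Aspartate and nucleotide synthesis held 7 higher and 9 lower of 25 genes in both countings, with Got1 (1.45 ± 0.08) higher and Gmps (-1.13 ± 0.09) lower. Its mean was -0.01, its median 0.08 and the test pointed up (adjusted p = 0.703), and Gmps was not called after the GC and length adjustment (-0.13).

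Genes of cholesterol synthesis fell, 12 of 25 lower and 1 higher in both countings, with Idi1 (-1.64 ± 0.13) and Sqle (-0.85 ± 0.09) among them and Hmgcs1, the synthase ahead of the rate-limiting step, down from 106 ± 1.17 to 44.7 ± 4.97 CPM. The mean was -0.35 (camera adjusted p = 0.0399; adjusted p = 0.234 with an estimated correlation; adjusted mean -0.42). The call was lost without knockout vehicle replicate 2 (adjusted p = 0.0823), without knockout oxybutynin replicate 2 (0.0521) and with only the 2 groups in the fit (0.0603). Fatty acid synthesis was not called (adjusted p = 0.426), with 8 of 16 genes higher and 3 lower in both countings, among them the elongase Elovl6 (-2.37 ± 0.10) and the acetyl-CoA synthetase Acss2 (1.65 ± 0.12). LXR targets were not called either (adjusted p = 0.0566), with 4 of 7 higher and 1 lower (5 and 1 adjusted over the list alone) and the phospholipid transfer protein Pltp up by 2.13 ± 0.10. Targets of the antioxidant factor NRF2 rose, 19 of 23 higher and 2 lower in both countings. Their mean was 0.76 (camera adjusted p = 4.48e-05; adjusted p = 0.156 with an estimated correlation; adjusted mean 0.69). Haem oxygenase Hmox1 rose from 83.3 ± 5.01 to 361 ± 29.6 CPM, and the quinone reductase Nqo1 (2.14 ± 0.10) and the glutathione transferase Gsta4 (1.97 ± 0.10) rose as well. Lysosome genes rose in 25 of 29 cases with 0 lower in both countings, among them Gpnmb (from 38.0 ± 1.95 to 248 ± 12.4 CPM), the lysosomal enzyme gene Hexa (2.41 ± 0.10) and cathepsin Ctsb (1.23 ± 0.08). The lysosome mean was 0.94 (camera adjusted p = 3.72e-09; adjusted p = 0.156 with an estimated correlation; adjusted mean 0.81).

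Transcripts of the other complex III genes did not fall with Uqcrfs1 as a group. Of 15 subunit and assembly genes, Uqcrfs1 included, 7 rose and 2 fell in both countings, and Uqcrfs1 was 1 of the 2 lower. The core subunit Uqcrc1 was at 0.83 ± 0.11 and the assembly factors Bcs1l at 0.76 ± 0.10 and Uqcc1 at 0.64 ± 0.08. The list was not called (adjusted p = 0.141), and its mean of -0.03, which includes Uqcrfs1, differed in sign from its median of 0.29 and from the test, which pointed up. Nuclear genes of complex I held 17 higher and 3 lower of 36 (14 and 2 adjusted over the list alone; list adjusted p = 0.0512), with Ndufs7 (0.91 ± 0.08) and Ndufa10 (0.78 ± 0.08) higher and Ndufb2 (-1.51 ± 0.23) lower. Their mean of 0.24 became 0.03 after the GC and length adjustment, with 10 higher and 4 lower. Complexes II, IV and V held 9 higher and 2 lower of 26 (7 and 2 adjusted over the list alone; list adjusted p = 0.169), with the complex II subunit gene Sdhc at 0.66 ± 0.09. Mitochondrial ribosomal proteins rose in 22 of 41 cases and fell in 5 in both countings, with Mrps23 at 0.82 ± 0.11 and Mrpl10 at 0.60 ± 0.09. The list mean was 0.20 (camera adjusted p = 0.0205; adjusted p = 0.52 with an estimated correlation), and the call was lost after the GC and length adjustment (14 higher and 9 lower, mean 0.14, adjusted p = 0.151) and with protein-coding genes alone (adjusted p = 0.0765). Of 10 measured genes of the mitochondrial genome 1 rose and 5 fell in both countings, beside mitochondrial shares of 3.11% in floxed and 2.23% in knockout vehicle. The complex III subunit gene mt-Cytb was at -1.37 ± 0.10 and mt-Nd5 at -1.53 ± 0.13. That list was not called (mean -0.60, adjusted p = 0.102), and after the GC and length adjustment 6 were higher and 3 lower, with a mean of 0.34. Cytosolic ribosomal protein genes held 17 higher and 0 lower of 42 (15 and 0 adjusted over the list alone), with a mean of 0.19 (list adjusted p = 0.0823). After the adjustment 8 were higher and 16 lower, with a mean of -0.08.

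Mitosis genes fell. Of 36 measured members 23 fell and 1 rose in both countings. Mki67 was at -2.72 ± 0.10, the kinetochore gene Cenpf at -2.43 ± 0.12, the kinesin Kif23 at -1.64 ± 0.09 and topoisomerase Top2a at -1.50 ± 0.09. The mean was -0.74 (camera adjusted p = 5.15e-05; adjusted p = 0.156 with an estimated correlation) and -0.59 after the GC and length adjustment. Several regulators of mitotic entry were not called, among them Ccnb1 (-0.02), Cdk1 (0.06), Aurka (0.04), Foxm1 (-0.02) and Plk1 (-0.19). S phase genes held 15 lower and 5 higher of 36 (15 and 4 adjusted over the list alone). They included cyclin Ccne2 (-2.16 ± 0.13), the polymerase gene Pola1 (-1.70 ± 0.12) and thymidylate synthase Tyms (-1.15 ± 0.10), and the licensing factor Cdt1 (0.95 ± 0.09) was higher. The list mean was -0.26 and it was not called (adjusted p = 0.102). It was called after the GC and length adjustment (mean -0.30, adjusted p = 0.0062, or 0.212 with an estimated correlation). DESeq2 (0.036), protein-coding genes alone (0.0394) and fry (0.000894) also gave a call. G1 cyclins and CDK inhibitors held 7 higher and 4 lower of 14 in both countings, with the inhibitor Cdkn2a (0.93 ± 0.12) higher and Cdk6 (-1.29 ± 0.10) and Cdkn1c (-1.05 ± 0.13) lower. Its mean was -0.05, its median 0.23 and the test pointed up (adjusted p = 0.819). The p53 targets held 6 higher and 6 lower of 21 in both countings (list adjusted p = 0.627). The p53 target and CDK inhibitor Cdkn1a was not called (-0.08 ± 0.12, adjusted p = 0.54). It was at -0.52 after the GC and length adjustment (adjusted p = 2.5e-05) and at 0.09, uncalled, without knockout vehicle replicate 2.

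Genes of the senescence-associated secretory phenotype rose in 10 of 13 cases and fell in 1 in both countings. The chemokine gene Ccl7 rose from 0.245 to 10.1 CPM (5.34 ± 0.23) and Igfbp7 by 2.38 ± 0.12. The list mean was 1.45 (camera adjusted p = 0.000389; adjusted p = 0.156 with an estimated correlation; adjusted mean 1.28). Collagen and matrix genes rose in 17 of 23 cases and fell in 3 (18 and 4 adjusted over the list alone). The proteoglycan Bgn (1.71 ± 0.08), the matricellular genes Thbs2 (1.85 ± 0.12) and Ccn2 (1.60 ± 0.10) and collagen Col6a1 (1.45 ± 0.10) were higher. Their mean was 0.75 (camera adjusted p = 0.000128; adjusted p = 0.156 with an estimated correlation; adjusted mean 0.61). Interferon-response genes were not called as a list (adjusted p = 0.174), with 6 of 17 higher and 1 lower (1 and 0 adjusted over the list alone), Bst2 among them at 1.29 ± 0.25. Markers of other cell types were measured too, since a primary culture can hold them. Those of fibroblasts and fibro-adipogenic progenitors rose in 5 of 6 cases with 0 lower in both countings (mean 1.38, camera adjusted p = 0.00486; adjusted p = 0.156 with an estimated correlation; adjusted mean 1.29). Their levels were low, with Cd34 going from 3.58 to 17.6 CPM and Thy1 from 0.451 to 1.74 CPM. Smooth muscle markers held 4 higher and 2 lower of 8 (6 and 2 adjusted over the list alone), with Tagln at 1.96 ± 0.14 and Acta2 at 1.03 ± 0.10. That list was not called (adjusted p = 0.0925). It was called after the GC and length adjustment (adjusted p = 0.0471, or 0.212 with an estimated correlation). DESeq2 (0.0119), no filter (0.0106), leaving out floxed vehicle replicate 3 (0.0408) and fry (0.000145) also gave a call. Endothelial markers (2 of 5 higher, 0 lower in both countings; adjusted p = 0.174) and leukocyte markers (3 of 8 higher, 1 lower in both countings; adjusted p = 0.251) were not called as lists. The macrophage marker Cd68, also a lysosomal protein, rose by 1.19 ± 0.13. With 3 measured genes each, adipocyte markers (3 higher in both countings, Lpl at 1.08 ± 0.12) and Schwann cell markers (1 lower in both countings, Erbb3 at -1.17 ± 0.09) were counted and not tested as lists.

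The called genes of muscle differentiation were mostly lower. In the list of myogenic differentiation and the sarcomere 21 of 35 genes fell and 8 rose (21 and 9 adjusted over the list alone). Mymx, a myoblast fusion peptide, fell by 2.41 ± 0.15, Mef2c by 2.01 ± 0.10, the sarcomere gene Neb by 1.58 ± 0.09 and cardiac actin Actc1 by 1.54 ± 0.08, while skeletal actin Acta1 rose by 0.80 ± 0.10. The mean was -0.42 and the list was not called (adjusted p = 0.062), though it was after the GC and length adjustment (mean -0.60, adjusted p = 0.00142; adjusted p = 0.424 with an estimated correlation). It was also called by DESeq2 (0.000252), by fry (0.00208), and with library totals (0.0443), no filter (0.0205) or protein-coding genes alone (0.0379). The same held without floxed vehicle replicate 2 (0.0293) or knockout vehicle replicate 1 (0.0219). In the full set the adjusted p was 0.628 with an estimated correlation. Of 22 satellite cell and myoblast identity genes 7 were higher and 9 lower (8 and 10 adjusted over the list alone; list adjusted p = 0.559). After the GC and length adjustment 3 were higher and 13 lower (list adjusted p = 0.0591). The growth factor receptor Met fell by 1.41 ± 0.09, the receptor Megf10 by 0.94 ± 0.08 and M-cadherin Cdh15 by 0.88 ± 0.10. Myog, the transcription factor that starts differentiation, fell by 0.55 ± 0.09 on the log2 scale (adjusted p = 2.3e-05). Pax7, the factor of satellite cells, rose by 0.26 ± 0.07 (adjusted p = 0.0042) but was -0.09 after the GC and length adjustment. Myod1, the myoblast factor, was not called (0.22 ± 0.10, adjusted p = 0.076). It was called at 0.35 without knockout vehicle replicate 2 and, in the opposite direction, at -0.37 after the GC and length adjustment. Of the muscarinic receptors that oxybutynin blocks, Chrm3 alone was abundant enough to test, at 669 counts summed over the 9 libraries (0.04 ± 0.19, adjusted p = 0.87). Chrm1, Chrm2, Chrm4 and Chrm5 summed to 9, 1, 45 and 0 counts.

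The list test fry, which does not set a list against other genes, called 27 of 33 lists with knockout. All 12 lists called by camera were among them. So were LXR targets (fry adjusted p = 4.73e-05, higher) and genes of the mitochondrial genome (0.00184, lower). Some lists were called by camera neither before nor after the GC and length adjustment, which moved their means with knockout by different amounts. It took LXR targets from 0.90 to 0.61, leukocyte markers from 0.41 to 0.07, endothelial markers from 0.46 to 0.33 and complexes II, IV and V from 0.18 to 0.04. Complex III genes, Uqcrfs1 included, went from -0.03 to -0.13, G1 cyclins and CDK inhibitors from -0.05 to -0.23 and satellite cell identity genes from -0.31 to -0.42. Serine and one-carbon genes (0.31 and 0.32), mitochondrial chaperones and proteases (0.20 and 0.17), the unfolded protein response (0.17 and 0.18), fatty acid synthesis (0.10 and 0.08), interferon-response genes (0.42 and 0.40) and p53 targets (0.04 and 0.06) moved by 0.03 or less. Counts moved as well, to 6 higher and 6 lower in complexes II, IV and V, 4 and 7 for G1 cyclins and CDK inhibitors, 7 and 6 for fatty acid synthesis and 1 and 1 for leukocyte markers.

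**Figure D4:**
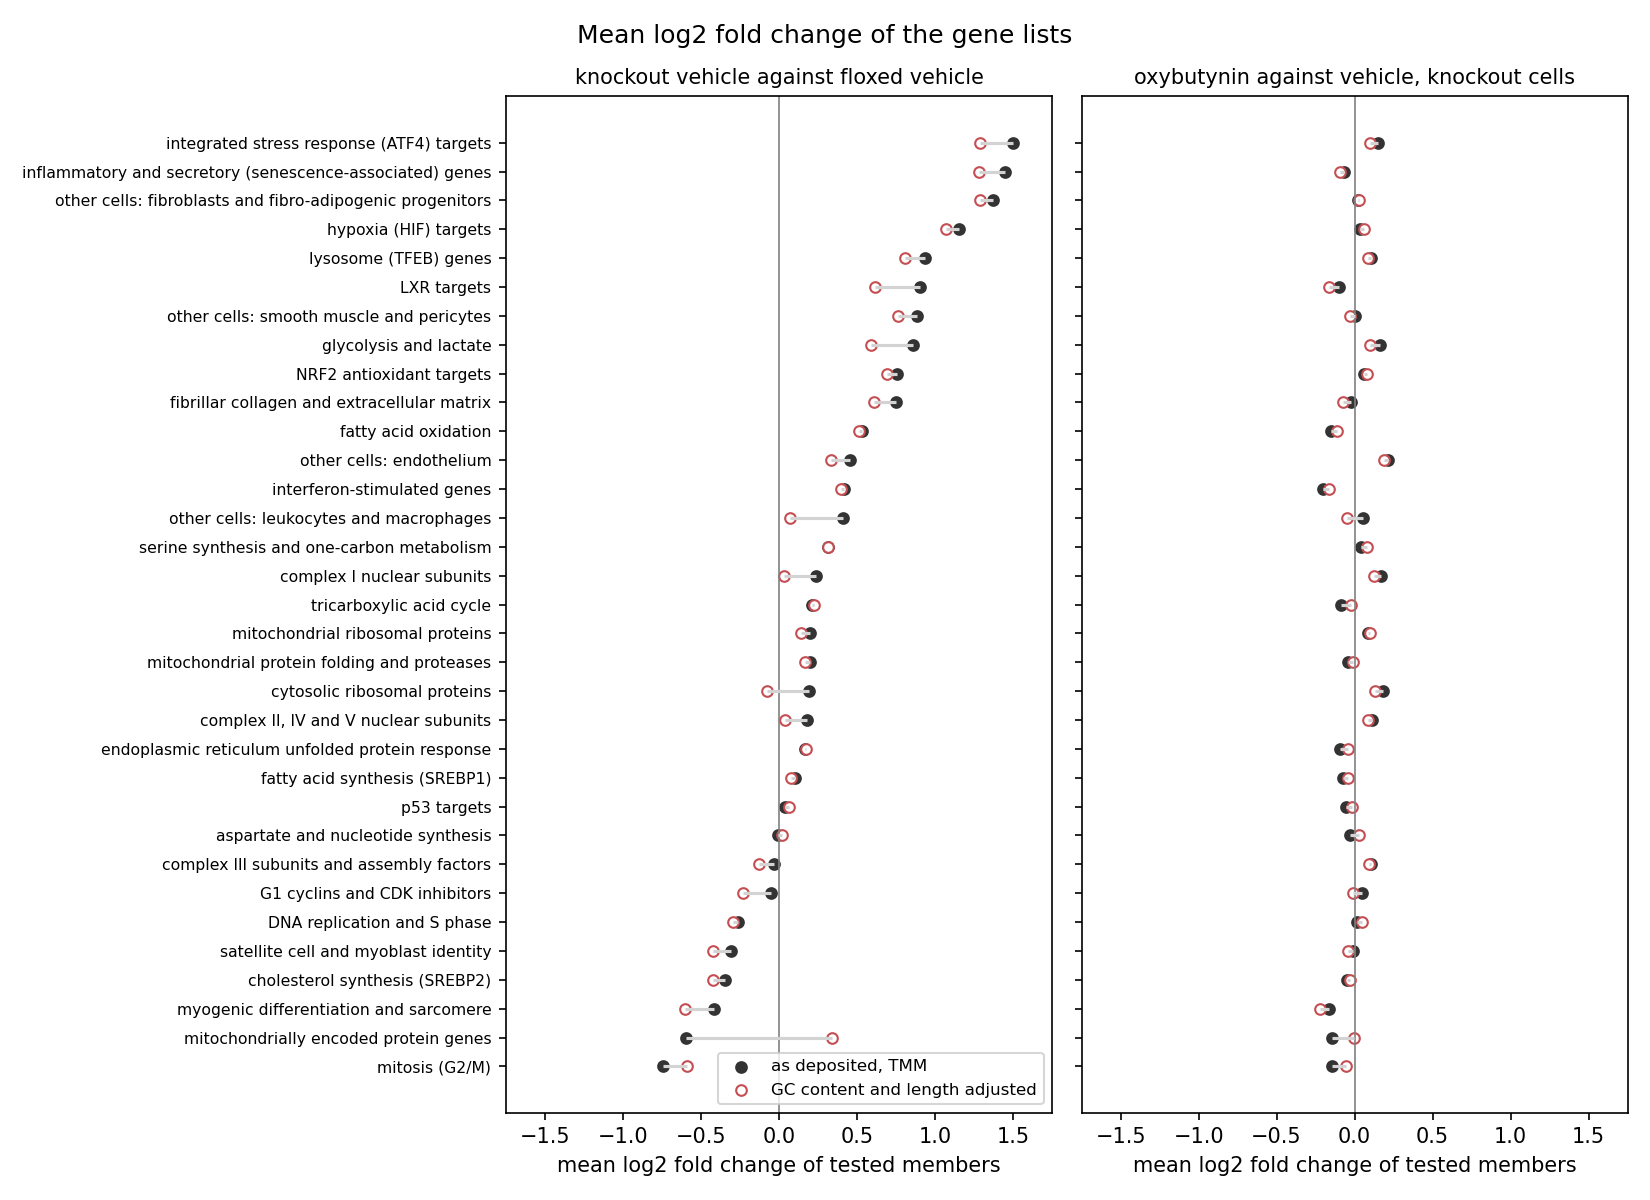
Mean log2 fold change (horizontal axis) of the measured members of each of the 33 tested gene lists (vertical axis) for knockout against floxed vehicle (left) and for oxybutynin against vehicle in knockout cells (right), before (filled) and after (open) the GC and length adjustment. The integrated stress response list lay at 1.5 and 1.29 on the left and at 0.15 and 0.10 on the right.

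To address how oxybutynin, which the submitters took from a compound screen on muscle cells with blocked complex III, acted on knockout cells, knockout oxybutynin was compared with knockout vehicle. Differences were small against those of the knockout, with a median absolute log2 fold change of 0.19 against 0.51. Ddit3 averaged 56.5 ± 5.50 CPM with oxybutynin and 47.6 ± 4.95 with vehicle, Gdf15 129 ± 14.8 and 107 ± 21, and Hk2 180 ± 7.43 and 179 ± 7.80. Hmox1 averaged 408 ± 33.4 and 361 ± 29.6, and none of these genes passed the test. Mki67 was at 72.9 ± 7.10 against 91.9 ± 7.57 CPM (-0.33 ± 0.09, adjusted p = 0.075), a difference called without knockout vehicle replicate 3 (-0.36, adjusted p = 0.017) and by DESeq2. Of 15720 genes 2 passed an adjusted p of 0.05. Neither met the rule for naming genes, and both were chosen after their values were seen. The small nucleolar RNA Gm24616 was higher (1.29 ± 0.19, adjusted p = 0.029) and the protein-coding gene AW551984 lower (-1.0 ± 0.14, adjusted p = 0.026). Both calls were lost without knockout vehicle replicate 1 or without any of the oxybutynin replicates (adjusted p of Gm24616 0.092, and 0.19, 0.093 and 0.086). In a fit of only the 2 groups compared 2 genes were called, both higher, so AW551984 lost its call there.

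The number of genes called with oxybutynin depended on single libraries and on the tool. At an unadjusted p under 0.05 there were 4084 genes (26%), 2168 after the GC and length adjustment and 2806 in a fit of only the 2 groups compared. The full fit also takes its spread from the floxed libraries. Those lay closer together (Pearson correlation of log2 CPM 0.9934 to 0.9938) than the knockout vehicle ones (0.9849 to 0.9898), so its p-values between the knockout groups may be too small. The smaller fit also has fewer residual degrees of freedom, and these effects were not told apart. Before the adjustment, 3477 genes (22.1%) had no overlap between the groups, where chance gives 10% on average over splits. Genes move together, so a given split can lie far from that average by chance. The edgeR test called 4188 genes (1873 higher, 2315 lower) without knockout vehicle replicate 3, the vehicle library nearest the oxybutynin ones. It called 63 (12 higher, 51 lower) without knockout vehicle replicate 2. Without knockout vehicle replicate 1 or any oxybutynin replicate it called 0, with 3611, 2555, 2937 and 3637 genes at an unadjusted p under 0.05 in those 4 fits. DESeq2 called 1157 genes (190 higher, 967 lower) in the full set. Of the library measures, ribosomal RNA loci took 12.1 ± 1.69% of counts with oxybutynin and 9.79 ± 2.10% with vehicle (exact two-sided permutation p = 0.3). In simulated counts the test recovered 68% of genes changed 1.5-fold and 96% of genes changed 2-fold between these groups. Those genes were drawn independently, with no spread shared by the genes of a library. Recovery in the real libraries may therefore be lower, and these shares do not limit how many genes changed.

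Among the gene lists, camera with a preset correlation placed 6 apart from other genes, while 0 members of any list passed the test over all genes. All 6 had an adjusted p of 0.785 with an estimated correlation, and fry called 0 lists. Of the 9 other splits of the same 6 libraries into equal groups, which mix treated and untreated cells, 7 gave at least as many called lists, up to 9. The number of lists called therefore does not set the drug apart from arbitrary groupings, and the preset-correlation p-values below carry that limit. Targets of ATF4 were higher by a mean of 0.15 (camera adjusted p = 0.00136), with 28 of 34 members positive. Adjusted over the list alone 10 were higher and 2 lower, and the amino acid transporter Slc7a5 (0.31), the glutathione-degrading enzyme Chac1 (0.29), Trib3 (0.37) and Atf4 (0.23) were among the higher ones. This call remained without each single library and after the GC and length adjustment (mean 0.10, adjusted p = 0.0057). Lysosome genes were higher by a mean of 0.10 (22 of 29 positive, 0 called over the list alone, camera adjusted p = 0.0121; adjusted mean 0.09), a call kept without each single library and lost with the adjustment and knockout vehicle replicate 2 left out together (0.0871). Cytosolic ribosomal protein genes were higher by a mean of 0.18 (38 of 42 positive, 1 called over the list alone, camera adjusted p = 0.00136; adjusted mean 0.13), a call lost without knockout vehicle replicate 2 (adjusted p = 0.319) or oxybutynin replicate 1 (0.095). Nuclear complex I genes were higher by 0.17 (29 of 36 positive, 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00379; adjusted mean 0.12), and that call was lost without knockout vehicle replicate 2 (0.637). Glycolysis genes were higher by 0.16 (18 of 22 positive, 0 called over the list alone, camera adjusted p = 0.0121; adjusted mean 0.10), which was lost without knockout vehicle replicate 2 (0.192) or oxybutynin replicate 1 (0.0824).

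Mitosis genes were lower with oxybutynin by a mean of -0.15 (25 of 36 negative, camera adjusted p = 0.0213; adjusted p = 0.785 with an estimated correlation). Adjusted over the list alone 15 were lower and 2 higher, with the kinetochore gene Spc25 at -0.60, Top2a at -0.37 and Mki67 at -0.33, and the mitotic kinase Plk1 at 0.24 and the transcription factor Foxm1 at 0.20. The call was lost without knockout vehicle replicate 1 (adjusted p = 0.104) and after the GC and length adjustment (mean -0.05, adjusted p = 0.0564). Sarcomere genes had a mean of -0.16 and were not called (26 of 35 negative, adjusted p = 0.0668). Adjusted over the list alone 7 were lower, such as the actin filament protein Lmod3 at -0.69, the myosins Myh8 at -0.55 and Myh1 at -0.49, and Mef2c at -0.34. The list was called without knockout vehicle replicate 2 (3.61e-05), without oxybutynin replicate 2 (0.0235), by DESeq2 (3.2e-05), with library totals (0.0247), with no filter (0.0219) and after the GC and length adjustment (mean -0.22, adjusted p = 1.55e-07; adjusted p = 0.483 with an estimated correlation). Fatty acid oxidation (mean -0.15, adjusted p = 0.0748) was called by DESeq2 (0.00394), without knockout vehicle replicate 2 (0.00682) and after the adjustment (mean -0.11, adjusted p = 0.029; adjusted p = 0.483 with an estimated correlation). Mitochondrial ribosomal proteins (mean 0.09, adjusted p = 0.0519) were called without knockout vehicle replicate 1 (0.00653) or 3 (0.0215), without oxybutynin replicate 2 (0.0451) or 3 (0.0388) and after the adjustment (mean 0.10, adjusted p = 0.00891; adjusted p = 0.483 with an estimated correlation). They were also called by DESeq2 (0.00395), with no filter (0.0436), at a mean of 1 CPM (0.0466) and with protein-coding genes alone (0.0398). Serine and one-carbon genes (adjusted p = 0.551) and NRF2 targets (0.291) were called after the adjustment, each at a mean of 0.08 (0.0444 and 0.0396; adjusted p = 0.483 for both with an estimated correlation). Collagen and matrix genes (adjusted p = 0.955) were called after it at a mean of -0.07 (0.0396; adjusted p = 0.483 with an estimated correlation). Before the adjustment the adjusted p of all lists not called ran from 0.0519 to 0.955. In the lists of p53 targets, satellite cell identity, cholesterol synthesis, collagen and matrix, aspartate and nucleotide synthesis and fibroblast markers the mean and median differed in sign, with every one of these values between -0.055 and 0.063.

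Genes and lists moved by the knockout were compared with those moved by the drug, to ask whether oxybutynin turned knockout changes back. Of the 2 genes called with oxybutynin, Gm24616 was lower in knockout and higher with the drug and AW551984 was lower in both. These tallies of 1 gene in opposite directions and 1 in the same direction were 45 and 923 with DESeq2, 307 and 2655 without knockout vehicle replicate 3, and 0 and 0 with any 1 of the oxybutynin replicates or knockout vehicle replicate 1 left out. After the GC and length adjustment they were 2 and 11. For independent calls 0.633 genes would be found in opposite directions and 0.633 in the same direction. Of the 6 lists called with oxybutynin, those of ATF4 targets, lysosome, glycolysis and mitosis were also called with knockout, each in the same direction in both comparisons, and 0 lists were called in opposite directions by camera. With an estimated correlation none of the 4 was called in either comparison (adjusted p = 0.785 for each with oxybutynin; with knockout 0.234 for glycolysis and 0.156 for the others). The mitosis call with oxybutynin was also lost after the GC and length adjustment (0.0564). After the GC and length adjustment 2 lists were called in opposite directions, fatty acid oxidation and collagen and matrix. Both were higher with knockout and lower with oxybutynin, with camera adjusted p of 0.029 and 0.0396 for the drug. Their adjusted p was 0.483 with an estimated correlation. Called in the same direction after the adjustment were ATF4 targets, lysosome, glycolysis and NRF2 targets, higher in both, and sarcomere genes, lower in both. With an estimated correlation none of these was called with oxybutynin either. Both comparisons use the knockout vehicle libraries with opposite signs, which gives opposite movement by chance alone. Over genes the covariance of the 2 sets of log2 fold changes was 0.0647, against -0.0208 in simulations of unchanged groups. Those simulations hold no knockout effect and no spread shared by genes. Of the 19 other ways to group the 6 knockout libraries into 3 and 3, a test chosen after the result was seen, 1 gave a covariance as large, at 0.0653. The 3 knockout vehicle libraries were not split between the comparisons, since a part would have held 1 library.

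How far treated knockout cells lay from untreated floxed cells was read from knockout oxybutynin against floxed vehicle, in which genotype, virus and drug all differ. Trib3 averaged 188 ± 13.9 CPM in treated knockout cells and 15.2 ± 1.87 in floxed cells, Ddit3 56.5 ± 5.50 and 6.13 ± 0.567, and Hk2 180 ± 7.43 and 51.2 ± 1.96, all higher. Mki67 was 8.31-fold lower (-3.05 ± 0.10) and Mef2c fell from 171 ± 8.74 to 33.5 ± 4.37 CPM. Cdsn (4.75 ± 0.16), Xdh (4.28 ± 0.14), Sh2d6 (4.12 ± 0.22), Acot2 (3.84 ± 0.10) and Trib3 (3.63 ± 0.14) had the largest rises, and after Uqcrfs1 (-4.95 ± 0.13) the largest falls were those of Chml (-3.20 ± 0.11), Cep290 (-3.09 ± 0.16), Mki67 and the dynein adaptor Bicd1 (-3.04 ± 0.17). The edgeR test called 11303 of 15720 genes (71.9%), 5510 higher and 5793 lower. Groups did not overlap for 12407 genes (78.9%, against 10% by chance on average over splits). Ribosomal RNA loci took 12.1 ± 1.69% of counts in these knockout libraries and 8.07 ± 0.327% in floxed ones, and after the GC and length adjustment 9904 genes were called, 980 of them called in both fits with opposite sign.

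Camera with a preset correlation called 13 lists in this comparison, and 0 were called with an estimated correlation, which gave adjusted p between 0.149 for hypoxia targets and 0.658 for cytosolic ribosomal proteins. Targets of ATF4 rose by a mean of 1.65, with 31 of 34 genes higher and 2 lower (camera adjusted p = 6.37e-11; adjusted p = 0.253 with an estimated correlation). Lysosome genes rose by 1.04, with 25 of 29 higher and 2 lower (1.02e-07; adjusted p = 0.253 with an estimated correlation), and glycolysis genes by 1.02, with 21 of 22 higher and 1 lower (3.12e-06; 0.35 when estimated). NRF2 targets rose by 0.82 with 18 of 23 higher and 3 lower (0.000192; 0.253 when estimated) and hypoxia targets by 1.19 with 13 of 17 higher and 1 lower (0.000277; 0.149 when estimated). Matrix genes rose by 0.73 with 17 of 23 higher and 3 lower (0.00158; 0.264 when estimated), and secretory genes of senescence by 1.38 with 11 of 13 higher and 1 lower (0.00186; 0.253 when estimated). Fibroblast markers rose by 1.40 with 5 of 6 higher and 0 lower (0.0147; 0.253 when estimated), a call lost when genes needed a mean of 1 CPM (0.0507). Mitosis genes fell by 0.89 on average, 24 of 36 lower and 3 higher (camera adjusted p = 0.000283; adjusted p = 0.253 with an estimated correlation). Sarcomere genes fell by 0.58 on average, 22 of 35 lower and 9 higher (0.033; 0.605 when estimated). Nuclear complex I genes, such as Ndufs7 at 1.16, rose by 0.41 with 26 of 36 higher and 2 lower (0.00601; 0.605 when estimated), and cytosolic ribosomal protein genes by 0.38 with 28 of 42 higher and 2 lower (0.00614; 0.658 when estimated). Complex I genes had a mean of 0.16 after the GC and length adjustment, with 14 higher and 2 lower (adjusted p = 0.0638). Cytosolic ribosomal protein genes then had a mean of 0.05 with 12 higher and 11 lower (0.585). Neither list was then called, the other 11 were, and 5 lists gained a call, which took the called lists from 13 to 16. Cholesterol synthesis (mean -0.45, adjusted p = 0.00625 from 0.0888), satellite cell identity (-0.47, 0.027 from 0.557) and S phase genes (-0.25, 0.0482 from 0.375) were lower. Their adjusted p with an estimated correlation was 0.125, 0.125 and 0.345. Fatty acid oxidation (0.40, 0.0325 from 0.122) and serine and one-carbon genes (0.40, 0.0425 from 0.165) were higher, with an adjusted p of 0.125 and 0.361 with an estimated correlation. Mitochondrial ribosomal proteins rose by 0.29, with 22 of 41 higher and 5 lower (0.00881; 0.527 when estimated), and by 0.24 with 18 higher and 7 lower after the adjustment (0.0401). For the 13 lists called before the adjustment the counts were the same adjusted over the list alone, except for 3 lower lysosome genes. Complex III genes, Uqcrfs1 included, had a median of 0.50 and a mean of 0.07, and were not called. The assembly factor Bcs1l was at 0.98 and the cytochrome gene Cyc1 at 0.81. Means and medians differed in sign for aspartate and nucleotide synthesis (-0.04 and 0.14), G1 cyclins and CDK inhibitors (-0.0023 and 0.17) and p53 targets (-0.02 and 0.08), where the test pointed up and called none. In this comparison Myod1 (0.45 ± 0.10) and Pax7 (0.39 ± 0.07) rose, but they lay at -0.36 and -0.11 after the GC and length adjustment.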

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

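The GC and length adjustment, with and without knockout vehicle replicate 2, the restriction to protein-coding genes and the adjusted p under 0.1 were chosen after seeing the data; all other settings were fixed before. No paired analysis was possible because the labels pair no libraries. Unless a cause follows from fewer libraries or genes, the cause was not tested. The fall of Uqcrfs1 with knockout kept its direction and its call under every alternative run, from -5.13 to -4.92 with each library left out. Depth limits genes like Chrm3, at 669 counts over 9 libraries.

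With each library left out, called genes ranged from 8950 to 10994 for knockout against floxed vehicle, from 0 to 4188 for oxybutynin against vehicle and from 10444 to 12051 for knockout oxybutynin against floxed vehicle. Called lists ranged from 11 to 16, from 4 to 9 and from 13 to 14. Genes called in opposite directions by knockout and drug ranged from 0 to 307, genes called in the same direction from 0 to 2655, and lists in opposite directions from 0 to 1. The high ends for single genes of the drug came without knockout vehicle replicate 3.

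For knockout against floxed vehicle, 6463 genes (2604 higher, 3859 lower) passed with at least 1.5-fold, against 9957 without that limit. Called lists went from 12 to 21 with DESeq2, 25 with no filter, 19 with the GC and length adjustment without knockout vehicle replicate 2, 0 with an estimated correlation and 27 with fry. For knockout oxybutynin against floxed vehicle they went from 13 to 20 with DESeq2, 20 with no filter, 0 with an estimated correlation and 29 with fry.

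For oxybutynin against vehicle the 2 called genes became 1157 with DESeq2 (190 higher, 967 lower, 1 of the 2 among them), 7 with RLE (2 and 5), 158 with library totals (10 and 148), 1099 with no filter (277 and 822), 13 without mitochondrially encoded genes (2 and 11), 15 with the GC and length adjustment (8 and 7), 20 with that adjustment without knockout vehicle replicate 2 (9 and 11), 1 with protein-coding genes only, 1189 at an adjusted p under 0.1 (279 and 910) and 0 at an adjusted p under 0.01 in edgeR, where 4084 had an unadjusted p under 0.05. The higher share was thus 50% with TMM, 28.6% with RLE, 6.33% with library totals and 16.4% with DESeq2. Called lists went from 6 to 14 with DESeq2, 11 with the GC and length adjustment (5 of the 6 among them), 3 with it without knockout vehicle replicate 2 (ATF4 targets higher, sarcomere and fatty acid oxidation lower), 0 with an estimated correlation and 0 with fry. For knockout against floxed vehicle the adjustment moved log2 fold changes by a median over genes of -0.09 with all libraries and -0.10 without that library.

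Genes called in opposite directions by knockout and drug, 1 with edgeR, were 45 with DESeq2, 0 with limma-voom, 7 with library totals, 66 with no filter, 0 with only the groups compared, 2 without mitochondrially encoded genes, 2 with the GC and length adjustment, 6 with it without knockout vehicle replicate 2 and 0 with protein-coding genes. Genes called in the same direction, also 1, were 923 with DESeq2, 3 with RLE, 128 with library totals, 813 with no filter, 0 with only the groups compared, 9 without mitochondrially encoded genes, 11 with the adjustment and 14 with it without that library. Lists called in opposite directions were 2 with DESeq2, 2 with the adjustment and 1 with it without that library, against 0.

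The 46 list results counted here are those called by camera before or after the GC and length adjustment. Of these, 27 kept direction and call under the adjustment, 15 gained a call, 4 lost it and 0 reversed. The gains are in the set by that rule. Lists called in neither fit were left out, and some of them changed direction, such as mitochondrially encoded genes with knockout (mean -0.60 before, 0.34 after). Under the same adjustment 155 of 176 named genes kept direction and call, 1 gained a call, 12 lost it and 8 reversed. With RLE all 46 and 176 kept both, and with limma-voom 46 and 175 did. The collagen and matrix list reversed its uncalled direction with oxybutynin at a mean of 1 CPM (adjusted p = 0.992) and with protein-coding genes (0.971), and without knockout vehicle replicate 1 (0.993), replicate 3 (0.889) or oxybutynin replicate 3 (0.697), within a leave-one-out range of adjusted p from 0.624 to 0.993.

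Reversed genes under the adjustment, and then under it without knockout vehicle replicate 2, were these. For knockout against floxed vehicle Chrm3 was at -0.11 and -0.10 (and -0.020 with protein-coding genes), Myod1 at -0.37 and -0.34 and Pax7 at -0.094 and -0.14. For oxybutynin against vehicle Myog was at -0.11 and -0.042, Pax7 at -0.015 (only in the former), and Cdkn1a at -0.071 and Myod1 at -0.0012 (only in the latter). For knockout oxybutynin against floxed vehicle Cdkn1a was at -0.48 and -0.48, Myod1 at -0.36 and -0.35 and Pax7 at -0.11 and -0.11. With library totals Uqcrfs1 was at -0.0021 between the knockout groups. With each library left out, Cdkn1a ranged from -0.18 to 0.087 with knockout and from -0.0025 to 0.26 with oxybutynin, Chrm3 from -0.11 to 0.21 with knockout and Uqcrfs1 from -0.028 to 0.19 with oxybutynin.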

Other observations

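The tests of undeleted cells and of shared knockout vehicle libraries, the regrouping of the knockout libraries, the GC and length adjustment and its use without knockout vehicle replicate 2 were chosen after the results they bear on were seen.

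Genes named in this paragraph were chosen after their values were seen. After the GC and length adjustment edgeR called 15 genes between oxybutynin and vehicle in knockout cells, 7 of them lower. The lower ones included the myosin-binding protein Mybpc1 (-0.56, adjusted p = 0.030), the actin filament protein Lmod3 (-0.63, 0.032), the fatty acid carrier Fabp3 (-0.44, 0.037), the troponin Tnnc2 (-0.54, 0.037) and skeletal actin Acta1 (-0.33, 0.037). Before the adjustment they were not called, with Mybpc1 at -0.64 (adjusted p = 0.0509), Lmod3 at -0.69 (0.0509), Fabp3 at -0.24 (0.168), Tnnc2 at -0.34 (0.143) and Acta1 at -0.12 (0.475). Of the 7, 3 belong to the sarcomere list (Lmod3, Tnnc2 and Acta1), in which 30 of 35 genes were negative after the adjustment (mean -0.22, camera adjusted p = 1.55e-07; adjusted p = 0.483 with an estimated correlation). Of the 8 higher genes, 4 were small nucleolar RNAs, among them Gm24616 (1.28, adjusted p = 0.0012) and Snora23 (0.74, 0.0068). Of 76 measured small nucleolar RNAs 61 were positive before the adjustment (median 0.41) and 51 after it (median 0.16), beside the ribosomal RNA shares of 12.1 ± 1.69% and 9.79 ± 2.10%. Their median with knockout was -0.06.

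In the mitochondrial genome, mt-Nd6, the protein gene of the light strand, was at 1.79 ± 0.19 with knockout, while the heavy-strand genes mt-Nd5 (-1.53 ± 0.13) and mt-Nd4 (-1.73 ± 0.17) fell. Since mt-Nd6 overlaps mt-Nd5 on the opposite strand and the strand setting of the counting is not given, its value is uncertain. After the GC and length adjustment mt-Nd6 was at 3.13 and mt-Nd4 at -0.75.

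Knockout vehicle replicate 2 lay nearer the floxed libraries, at 74.3% of the way from floxed to oxybutynin libraries, where the other 5 knockout libraries lay at 89.5% or more. An admixture of floxed cells would need a share of 19.4% and so 18.0 CPM of Uqcrfs1, but the library held 2.13 CPM against 2.61 in the other knockout vehicle libraries, which argues against undeleted cells. GC content and gene length bias remains open. Across protein-coding genes, the deviation from the group mean had a Spearman correlation with GC content of -0.628 in replicate 2. It was 0.113 and 0.615 in knockout vehicle replicates 1 and 3. After the trend was removed replicate 2 lay at 87.1%, below the lowest of the others (90.6%) by 3.55, less than their range of 11.2. Its place may therefore be due in part to the trend. No biological explanation was tested, since the labels give none for this library.

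Across genes the oxybutynin fold changes ran with the knockout fold changes, with a covariance of 0.0647 (correlation 0.254), above the -0.0223 to -0.0193 of simulations of unchanged groups. Those simulations hold no knockout effect and no library spread shared by genes, so exceeding them excludes none of the explanations, and of the 19 other ways to group the 6 knockout libraries 1 gave a covariance as large (0.0653). Shared knockout vehicle libraries that lay by chance nearer the floxed ones, replicate 2 among them, therefore stay open: without replicate 2 the covariance was 0.0105, and 1 of 9 other groupings gave as much (0.0123). GC content and gene length bias stays open too, since after the trend was removed the covariance was -0.000873, with 1 of 19 other groupings as large (0.00286). A small effect of the drug in the direction of the knockout may also be part of it, a hypothesis that was not tested apart from these.

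The rise of ATF4 targets and the fall of mitosis genes with knockout were weighed against GC content and gene length bias. After the trend was removed the ATF4 list had a mean of 1.29 (camera adjusted p = 2.93e-15; adjusted p = 0.0838 with an estimated correlation) against 1.5 before, and the mitosis list a mean of -0.59 (1.59e-06; 0.0489 estimated) against -0.74. These values argue against the trend as the whole cause of either. The groups also differ in the virus given, Cre or green fluorescent protein, which the design does not separate from loss of Uqcrfs1, so a response to Cre stays open beside the hypothesis that loss of complex III is the source.

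The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. Every other split mixes the groups, so a large real difference enters the spread within groups. For the comparisons with floxed cells, 0 called genes in other splits was thus nearly fixed in advance and says little about chance. Counting the real split, a result as large came for knockout against floxed vehicle from 1 split for genes (9957, highest of the 9 others 0) and from 4 for lists (12, highest other 13). For oxybutynin against vehicle it came from 1 split for genes (2, highest other 0) and from 8 for lists (6, highest other 9). The number of lists called with oxybutynin thus did not set the real split apart from the others. For knockout oxybutynin against floxed vehicle it came from 1 split for genes (11303, highest other 0) and from 4 for lists (13, highest other 14).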
